A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

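The libraries hold total RNA of log-phase yeast, extracted with hot acid phenol, treated with DNase, depleted of ribosomal RNA and made into Illumina libraries, per the labels' protocols. The authors deposited 1 table of 7130 rows with an FPKM value per library, meaning fragments per kilobase of transcript per 1e6 mapped fragments. Per the submitters' processing notes, TopHat2 and Cufflinks were used with the genome build sacCer2. Their versions and settings, the annotation and the handling of strand are not given in the sources used here. Groups and replicate numbers come from the sample titles, and each value column was tied to its sample by the description label, with 0 value columns unused. Coordinates are those of the deposited table, in the build sacCer2 of the submitters' notes, counted from 1.

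FPKM values are not counts, so no count model was used. For each library a depth was estimated from low ORF rows of 350 to 3000 bp holding 0.5 to 8.5 fragments, as the depth at which most values became whole fragments within 0.1, after taking 204 bp off each row's length. At the estimated depths 90.2%, 86.2%, 86.9% and 85.9% of the rows used (51, 58, 61 and 64 rows) were whole. The same scan on values moved by random factors, added after the data were seen and run 20 times, reached 31.7% to 50% with a median of 38.2%. The depths served to give a floor of 3 fragments and not to test. The summed FPKM was 5369809 and 4870207 in the WT libraries and 3742848 and 3777252 in the Asr1-RING libraries, and the median row was at 21.18, 19.92, 21.38 and 21.66 FPKM.

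Values were analysed as log2(FPKM + 1), with a pseudocount of 1, over rows with a mean of at least 1 FPKM across the 4 libraries. A log2 difference on this scale understates the change of low rows, and folds in the text are ratios of mean FPKM. This left 6892 rows, of which 6517 are ORFs, 266 tRNAs, 81 small nucleolar or spliceosomal RNAs, 14 ribosomal RNAs and 14 other non-coding RNAs. Asr1-RING was compared with WT by limma's moderated test with an intensity trend, 2 residual and 3.71 prior degrees of freedom, and Benjamini-Hochberg adjustment. A row was called at an adjusted p under 0.05. Gene lists with at least 5 tested members were tested with limma's camera, preset inter-gene correlation 0.01, adjusted over the 24 lists tested, and again with an estimated correlation and with fry. Counts adjusted over a list alone are given where they differ from those adjusted over all rows. All adjusted p-values for single rows are from limma.

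The lists, the rule for named genes, the tests and most alternatives were fixed before the data were examined. The rule named ASR1 and UBP3, then the 12 called rows with the largest log2 difference in each direction whose mutant libraries both lay on 1 side of both WT libraries, then up to 4 members with the smallest p of each list described. Falling ORFs and members outside the rule were named after their values were seen. Matching of list names to rows was widened to names without parentheses and to symbols and synonyms of the reference annotation after values had been seen, and no list's call changed. The tests of the phosphate genes for copies and position count calls, a change from a bound on the median made after the medians were seen. The chromosome ends of sacCer2 were not to hand, so the set near ends is the planned fallback of the 10 outermost rows at each of 32 ends. It was tested with camera and, for its share of calls, with Fisher's exact test.

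The reference annotation R64 gave gene names and sequences and no coordinates. Of the rows, 6048 matched it by identifier. Rows with a BLAST match to another row at 90% identity or more over at least 50% of their length, 368 in all, were treated as near-identical copies. Alternatives were pseudocounts of 0.1 and 5, no filter or a minimum mean of 10 FPKM, median centring, quantile normalization, moderation without a trend or robust, the replicate number as a block, each library left out in turn, an adjusted p under 0.1, a fold of at least 1.5, and sets of 5 or 15 outermost rows or without near-identical families. Tests on ORF rows alone and with rows of identical values counted once were added after the data were seen.

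The test was checked on simulated data with 6892 rows and 200 changed rows for the comparison of Asr1-RING with WT. Over 5 runs it recovered 70% of rows changed 1.5-fold, 97.2% of those changed 2-fold and 100% of those changed 4-fold, and 6.7% of all calls were false. Camera called 0 of 50 unchanged lists of 20 rows and 50 of 50 lists moved by 0.3 on the log2 scale. Rows were simulated independently of each other and lists were drawn at random. The check therefore does not cover real lists whose members vary together, such as the phosphate list with an estimated correlation of 0.406. Nor does the rate of false calls cover rows that vary together. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, R 4.3.3 with limma 3.58.1, and BLAST 2.17.0 were used. Values of rows shorter than a sequenced fragment depend on the effective length used upstream, which is not given in the sources used here, so levels of tRNAs and small nucleolar RNAs are compared only between libraries. Such comparisons assume the same effective length in every library, which was not tested.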

Results

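Total RNA of the budding yeast Saccharomyces cerevisiae was sequenced after depletion of ribosomal RNA, from cells in log phase at an optical density near 0.8 in enriched medium. There were 4 libraries, 2 from cells labelled wild type (WT) and 2 from cells labelled Asr1-RING, a mutant of the RING of Asr1. Asr1 is a RING-finger ubiquitin ligase known to act on RNA polymerase II. The comparison asks how the transcriptome differs between the mutant and WT and, as known of the study, whether genes near chromosome ends differ in expression. Low values lay on steps of whole fragments, which gave estimated depths, in units of 1e6 fragments, of 47.8 and 41.4 for WT replicates 1 and 2 and of 43.6 and 45.5 for Asr1-RING replicates 1 and 2. At these depths 3 fragments on a row of 1 kb correspond to 0.079, 0.091, 0.087 and 0.083 FPKM, a floor that covers counting error only. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Pearson's r of log2(FPKM + 1) over the 6892 tested rows was 0.991 within each group and 0.976 to 0.984 between groups, across rows that are not independent replicates. All means below are of 2 libraries and are given with their SD (n = 2).

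The mutated gene, ASR1 (YPR093C, chromosome XVI, 719556 to 720422), had 7.05 and 6.34 FPKM in the WT libraries and 4.99 and 5.39 FPKM in the Asr1-RING libraries. Its log2 difference was -0.31 (SE 0.115, limma adjusted p = 0.157) and did not pass the threshold. A change within its coding sequence cannot be read from a value per gene, so these levels do not check the labels. UBP3 (YER151C), a ubiquitin-specific protease reported to act against Asr1, had 8.15 ± 0.0702 FPKM in WT and 7.69 ± 1.04 FPKM in Asr1-RING (log2 difference -0.08, SE 0.123, limma adjusted p = 0.716). Without Asr1-RING replicate 2 the UBP3 difference was 0.04. All 4 libraries had the marker levels of alpha cells. The 4 alpha-cell genes MF(ALPHA)1, MF(ALPHA)2, STE3 and SAG1 ranged from 337 to 4300 FPKM, and the 7 a-cell genes from 2.4 to 67.2 FPKM. No marker passed the limma test, and 2 a-cell genes and 0 alpha-cell genes had an unadjusted p under 0.05.

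Genes of phosphate uptake and storage rose in the Asr1-RING libraries. PHO84 (YML123C, chromosome XIII, 24038 to 25801), the high-affinity phosphate transporter of the plasma membrane, rose from 18.6 ± 0.77 to 199.6 ± 64.4 FPKM. This is a 10.8-fold higher mean, with a log2 difference of 3.32 (SE 0.217, limma adjusted p = 0.0015). SPL2 (YHR136C), a regulator of low-affinity phosphate uptake, rose from 2.86 ± 1.01 to 14.3 ± 3.83 FPKM (log2 difference 1.99, adjusted p = 0.00793). VTC4 (YJL012C), a subunit of the polyphosphate polymerase of the vacuole, rose 1.93-fold, from 37.7 ± 0.79 to 72.6 ± 4.73 FPKM (adjusted p = 0.00399).

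The acid phosphatase genes PHO12 (YHR215W, chromosome VIII, 552099 to 553502) and PHO11 (YAR071W, chromosome I, 225451 to 226854) rose 4.64-fold and 4.10-fold (adjusted p = 0.0015 and 0.0022). PHO12 went from 3.78 ± 0.287 to 17.5 ± 2.22 FPKM and PHO11 from 3.66 ± 0.341 to 15 ± 2.35 FPKM. They are near-identical copies, so how much each contributed is uncertain. Of the 20 tested members of the phosphate list, 11 rose, 0 fell and 9 did not pass, and 13 rose with p-values adjusted over the list alone. Beside those already named, VTC1, VTC3, PHM6, PHO81, PHO86 and PHO89 rose. The median log2 difference of the list was 0.59 (camera adjusted p = 7.63e-08 with the preset correlation, adjusted p = 0.686 with an estimated correlation). The count of members called higher was 4 without WT replicate 1 and 4 without WT replicate 2. The VTC4 call was lost without either (adjusted p = 0.0567 and 0.0568), and the calls of PHO84, SPL2, PHO11 and PHO12 were not lost with any single library left out.

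**Figure D1:**
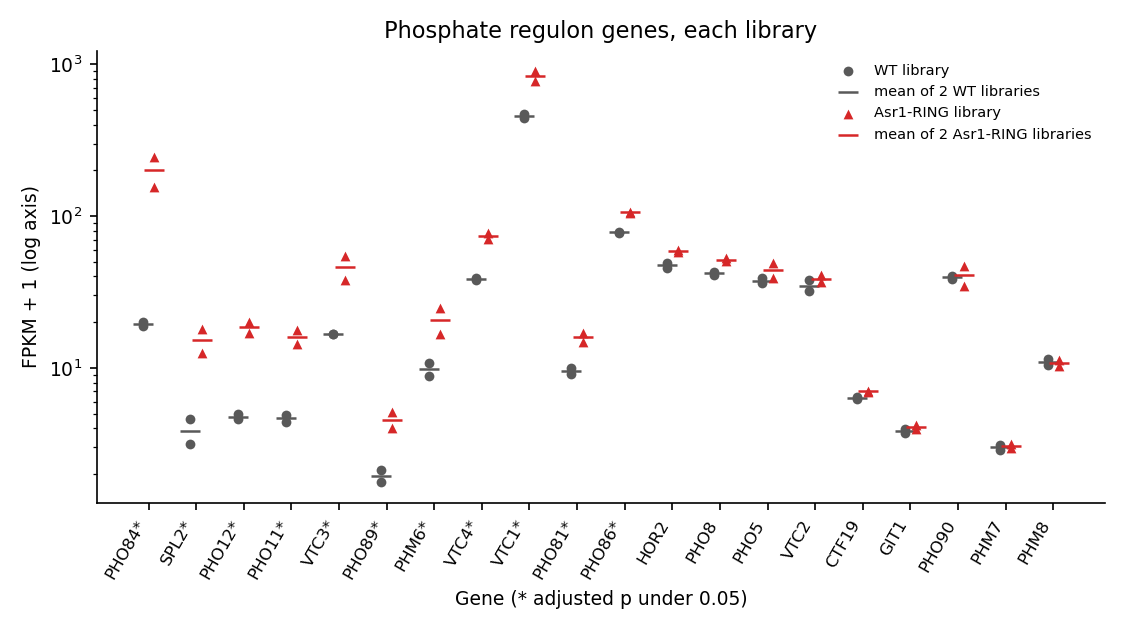
FPKM + 1 on a log axis for the tested genes of the phosphate list, with 1 grey circle per WT library, 1 red triangle per Asr1-RING library and a bar at the mean of the 2 libraries. PHO84 has 18 and 19.1 FPKM in the WT libraries and 245 and 154 FPKM in the Asr1-RING libraries.

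Transfer RNA values were lower in the Asr1-RING libraries. Of 266 tested tRNA rows 226 fell and 3 rose, with a median log2 difference of -1.47 (quartiles -1.79 and -1.23). Identical tRNA copies share their values, so these rows hold 88 distinct sets of values, of which 70 fell. HSX1 (tR(CCU)J, chromosome X, 538547 to 538618), an arginine tRNA, fell from 473.9 ± 48.9 to 67.7 ± 2 FPKM (log2 difference -2.79, SE 0.108, adjusted p = 0.00133). In Asr1-RING replicate 2 it had 66.3 FPKM, the value also listed for tP(UGG)N2. In WT replicate 2 it had 508.5 FPKM, the value also listed for the tRNA TRT2. Equal values in unrelated rows point to coarse steps, so HSX1 may rest on few fragments in Asr1-RING. The floor given for a row of 1 kb does not hold for rows this short. Threonine tRNAs with the anticodon AGU fell as well. Their 8 copies with equal values, among them tT(AGU)B and tT(AGU)C, were at 1437 and 1288 FPKM in WT and at 213.5 and 344.8 FPKM in Asr1-RING (log2 difference -2.32, adjusted p = 0.00363), and tT(AGU)N2 from 1410.2 ± 21.3 to 270.0 ± 79.9 FPKM (adjusted p = 0.0025).

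The alanine tRNA row tA(AGC)J fell from 552 ± 129 to 112.3 ± 44.6 FPKM (adjusted p = 0.00931), a call that ended without WT replicate 2 (adjusted p = 0.0517). The threonine tRNA row tT(UGU)H was listed at 91.5 and 247 FPKM in the WT libraries and at 0 in both Asr1-RING libraries. Like HSX1, tA(AGC)J, of 73 bp, and tT(UGU)H, of 72 bp, may rest on few fragments where their values are low. Over anticodons, 38 of 40 families had a median below 0 and 34 held at least 1 row that fell. The exceptions were tF(GAA), for phenylalanine, with a median of 0.64, and tS(GCU), for serine, with 0.11. The 3 tRNA rows that rose were tP(UGG)N2, tF(GAA)D and tF(GAA)N. The proline tRNA row tP(UGG)N2 was listed at 0 in both WT libraries and at 104 and 66.3 FPKM in the Asr1-RING libraries. It shares the value of 66.3 FPKM with HSX1 in Asr1-RING replicate 2, so this rise too may rest on few fragments. The rows tF(GAA)D and tF(GAA)N, named after their values were seen, are copies with equal values.

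Small nucleolar and spliceosomal RNAs were also lower. Of 81 tested rows of this class 55 fell and 0 rose, 77 had an unadjusted p under 0.05, and the median log2 difference was -0.73 (quartiles -0.94 and -0.58). SNR14, the U4 RNA of the spliceosome, fell from 6502 ± 578 to 4016 ± 174 FPKM, a 1.62-fold lower mean (adjusted p = 0.0194). SNR7-L, a form of the U5 RNA whose row overlaps SNR7-S, fell 1.48-fold (adjusted p = 0.0275). SNR30 and SNR128, both needed to process the precursor of 18S ribosomal RNA, fell 1.60-fold and 1.62-fold (adjusted p = 0.0275 and 0.0278). In the list of stable non-coding RNAs 6 of 18 members fell, 14 with p-values adjusted over the list alone. The list's median was -0.53 (camera adjusted p = 2.71e-07 with the preset correlation, adjusted p = 0.686 with an estimated correlation). Ribosomal RNA rows, whose RNA had been depleted, had a median of -0.80 over 14 rows, of which 0 passed limma's test and 8 had an unadjusted p under 0.05. That median was -0.46 with 6 rows lower without Asr1-RING replicate 1, -0.75 with 6 lower without Asr1-RING replicate 2, -1.06 with 2 lower without WT replicate 2, and -0.55 without WT replicate 1. It was -0.48 with identical rows counted once, and 2 rows were lower with median centring, robust moderation or a mean of at least 10 FPKM.

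The size of these falls depended on scaling. After quantile normalization the tRNA median was -1.10 with 180 rows lower, and the small nucleolar median was -0.27 with 18 rows lower and 1 higher. The list of stable non-coding RNAs lost its camera call under that scaling (median -0.03, adjusted p = 0.189), and 2 of its members were called lower without WT replicate 1. The count of small nucleolar rows called lower was 22 without WT replicate 1, 35 without Asr1-RING replicate 1 and 33 without Asr1-RING replicate 2. The SNR128 call ended without either mutant library (adjusted p = 0.306 and 0.311), that of SNR14 without WT replicate 1 (adjusted p = 0.102), and those of SNR30 and SNR7-L without WT replicate 1 (adjusted p = 0.11 and 0.151), WT replicate 2 (adjusted p = 0.0597 and 0.0705) or Asr1-RING replicate 2 (adjusted p = 0.163 and 0.072). As a share of the summed FPKM of a library, tRNA rows made up 9.5% and 9.06% in WT and 4.34% and 4.78% in Asr1-RING. Small nucleolar and spliceosomal rows made up 54.6% and 50.7% in WT and 44.9% and 44.1% in Asr1-RING. Values of rows this short depend on the effective length used upstream, so these shares serve only to compare libraries, provided that length was the same in each. They are not shares of RNA or of reads.

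**Figure D2:**
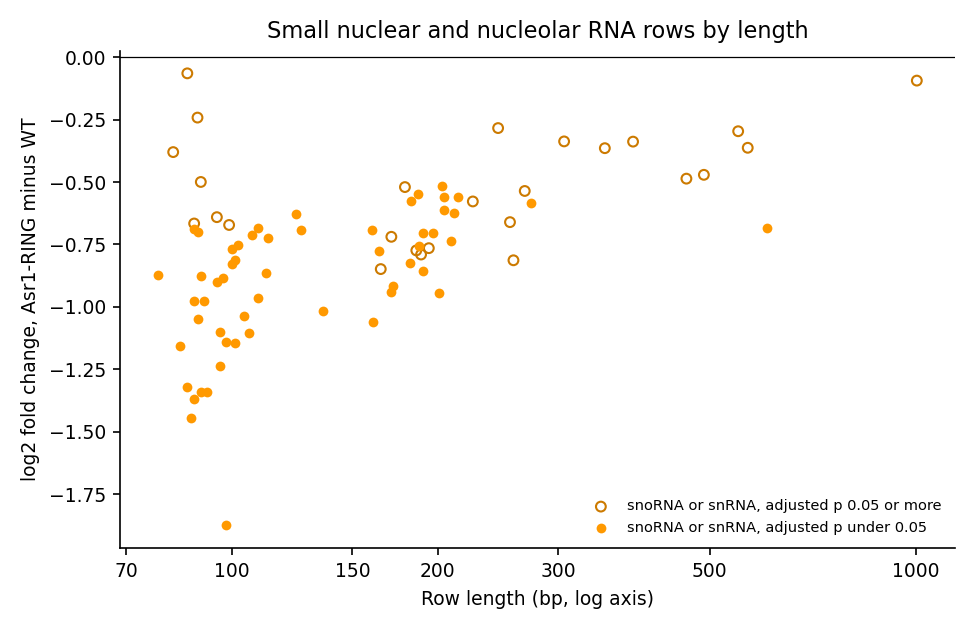
Log2 difference, Asr1-RING minus WT, against row length in bp on a log axis for the 81 small nucleolar and spliceosomal RNA rows, with filled points for rows that passed limma's threshold and open points for the others. The median is -0.89 for the 28 rows of up to 100 bp and -0.55 for the 22 rows over 200 bp.

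Over all classes, 130 rows were higher and 341 lower in Asr1-RING at an adjusted p under 0.05, of 6892 tested. Rows of open reading frames (ORFs) gave 127 of the higher and 60 of the lower calls among 6517, with a median log2 difference of 0.03. Of the ORF calls, 23 of the higher and 19 of the lower had means at least 2-fold apart, and 2 more of the higher are listed at 0 in WT. Higher calls made up 27.6% of all calls, against 13.5% (70 higher, 447 lower) with libraries centred on a common median and 49.3% (307 higher, 316 lower) after quantile normalization. When ORF rows alone were tested, an alternative added after the data were seen, 36 were higher and 23 lower. The counts rested on single libraries. They were 16 higher and 197 lower without WT replicate 1, 18 and 262 without WT replicate 2, 781 and 553 without Asr1-RING replicate 1, and 149 and 353 without Asr1-RING replicate 2.

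**Figure D3:**
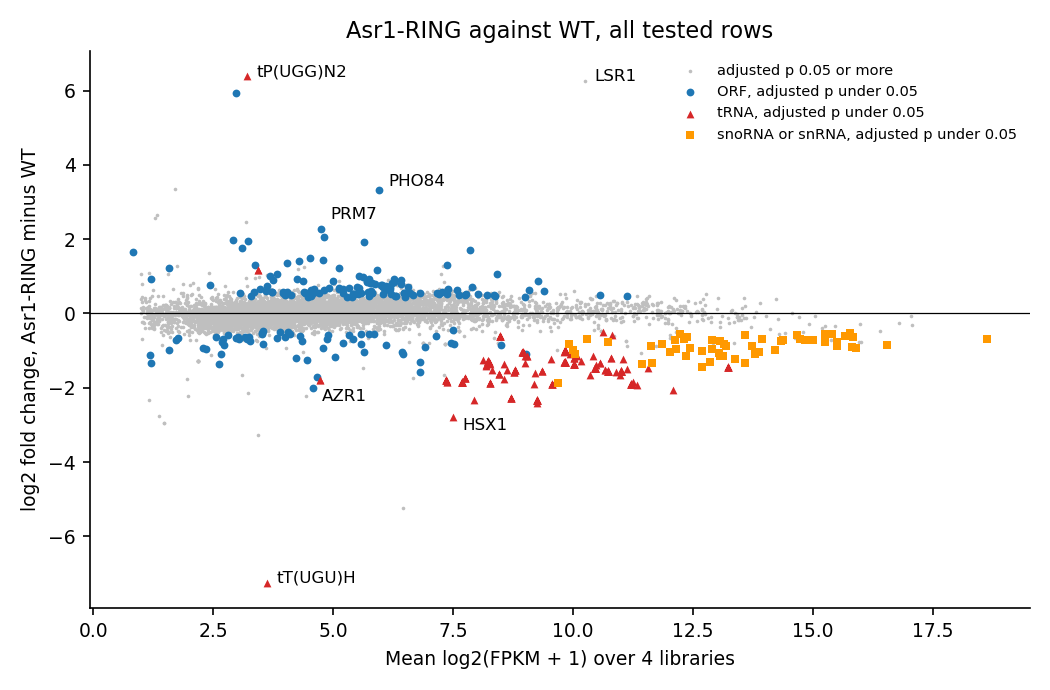
Log2 difference, Asr1-RING minus WT, against the mean log2(FPKM + 1) of the 4 libraries for the 6892 tested rows, with coloured symbols for ORF, tRNA, and small nucleolar or spliceosomal rows at an adjusted p under 0.05. Most coloured tRNA and small nucleolar points lie below 0, and LSR1, which did not pass, is labelled because 1 WT library lists it at 0.

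Among ORFs outside the phosphate list, PRM7 (YDL039C, chromosome IV, 381983 to 384079), a gene named for its regulation by pheromone, rose 5.21-fold, from 11.4 ± 3.56 to 59.2 ± 16.8 FPKM (log2 difference 2.28, SE 0.261, adjusted p = 0.00582). The overlapping pair YBR056W-A and YBR056C-B on chromosome II rose 4.40-fold and 3.29-fold (adjusted p = 0.00202 and 0.0015). They lie on opposite strands and strand handling is not given in the sources used here, so their reads cannot be told apart. YDR034W-B (chromosome IV, 521312 to 521467) rose 2.96-fold, from 12.8 ± 2.89 to 37.7 ± 10.2 FPKM (adjusted p = 0.017), and lost its call without WT replicate 2 (adjusted p = 0.0906). YKR075W-A, which overlaps YKR075C, rose from 25.2 ± 8.06 to 103.6 ± 54.6 FPKM (adjusted p = 0.0462), but its call was kept in 6 of 15 alternatives and ended without WT replicate 1 (adjusted p = 0.11) or WT replicate 2 (adjusted p = 0.216). A pair of short rows was listed at 0 in both WT libraries. These were YAR035C-A, at 105.4 and 33.7 FPKM in Asr1-RING, and YDR194W-A, at 2.19 and 2.10 FPKM. The row of YAR035C-A spans 81 bp, so its values may rest on few fragments.

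All 12 rows with the largest falls were tRNAs, so the 12 ORFs with the largest falls in log2 difference were named separately, after the values were seen. AZR1 (YGR224W, chromosome VII, 942809 to 944650), a plasma membrane transporter known from resistance to azoles and acids, fell from 46.6 ± 0.969 to 11.5 ± 5.59 FPKM, a 4.06-fold lower mean (log2 difference -2.01, SE 0.293, adjusted p = 0.0158). The AZR1 call ended without WT replicate 1 (adjusted p = 0.0974), without WT replicate 2 (adjusted p = 0.085) and with robust moderation (adjusted p = 0.0512). YLL056C, an uncharacterized gene, fell 2.29-fold (adjusted p = 0.011), a call that ended without WT replicate 1 (adjusted p = 0.0784) or 2 (adjusted p = 0.0837). The short ORF YBL071C-B fell 3.46-fold (adjusted p = 0.0015) and YLR365W, which overlaps YLR364C-A, fell 3.12-fold (adjusted p = 0.00248). YPR077C, which overlaps YPR078C, fell 5.84-fold (adjusted p = 0.03), YOR082C, which overlaps WHI5, 4.10-fold (adjusted p = 0.0316) and YOR293C-A 2.38-fold (adjusted p = 0.0194). Without WT replicate 1 these 3 calls ended (adjusted p = 0.141, 0.143 and 0.147), and without WT replicate 2 those of YOR082C and YOR293C-A (adjusted p = 0.1498 and 0.0664). The other 5 overlap a small RNA row. These were YOR072W-B over the tRNA SUF11 (adjusted p = 0.00267), YNL042W-B over tP(UGG)N1 (adjusted p = 0.00285), YPR108W-A over tT(UGU)P (adjusted p = 0.0275), IRC13 over SNR17A (adjusted p = 0.00582) and YJL047C-A over SNR60 (adjusted p = 0.0022), so their values are uncertain. The calls of IRC13 (adjusted p = 0.0621) and YPR108W-A (adjusted p = 0.18) ended without WT replicate 1, and that of YPR108W-A without WT replicate 2 (adjusted p = 0.135). Of the 60 ORFs that fell, 28 overlap another row, 8 of them a small RNA row.

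Genes of amino acid biosynthesis tended upwards. In this list 6 of 68 members rose, 0 fell and 62 did not pass, and 13 rose with p-values adjusted over the list alone. BAT1 (YHR208W), the mitochondrial branched-chain aminotransferase, rose 1.66-fold, from 185.6 ± 20.3 to 307.3 ± 26.9 FPKM (adjusted p = 0.0246). GDH1 (YOR375C), the NADP-dependent glutamate dehydrogenase, rose 1.49-fold (adjusted p = 0.0211), LEU1 of leucine synthesis 1.55-fold (adjusted p = 0.0403) and HIS1 of histidine synthesis 1.44-fold (adjusted p = 0.0379). GCN4, the transcriptional activator of this group, and SER33 rose as well. The list's median was 0.24 (camera adjusted p = 3.05e-06, adjusted p = 0.666 with an estimated correlation). No member was called without WT replicate 1 or without WT replicate 2, and 19 were called without Asr1-RING replicate 1. The HIS1 call ended without Asr1-RING replicate 2 as well (adjusted p = 0.0533).

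In the list of stress-induced genes 5 of 50 members rose, 0 fell and 45 did not pass, and 16 rose with p-values adjusted over the list alone. HSP26, a small heat-shock protein, rose from 12.7 ± 1.13 to 25.1 ± 2.69 FPKM (adjusted p = 0.00981). HXK1, a hexokinase, rose 2.07-fold (adjusted p = 0.0305), although its row overlaps YFR052C-A. GPH1, glycogen phosphorylase, whose row overlaps 2 others, rose 1.54-fold (adjusted p = 0.0376) and ALD4, the mitochondrial aldehyde dehydrogenase, 1.40-fold (adjusted p = 0.0355). The list's median was 0.23 (camera adjusted p = 0.000257, adjusted p = 0.666 with an estimated correlation). In the list of alcohol metabolism, which also holds ALD4, 3 of 22 members rose, 4 with p-values adjusted over the list alone. ALD5, a mitochondrial aldehyde dehydrogenase, rose from 63.9 ± 4.17 to 112 ± 0.663 FPKM (adjusted p = 0.00683), and ADH3, the mitochondrial alcohol dehydrogenase, rose 1.40-fold (adjusted p = 0.0441). This list's median was 0.16 (camera adjusted p = 0.0114, adjusted p = 0.666 with an estimated correlation, fry adjusted p = 0.0123). No member of either list was called without WT replicate 1 or without WT replicate 2. Without Asr1-RING replicate 1 the counts were 16 for stress and 5 for alcohol metabolism, and without Asr1-RING replicate 2 the calls of GPH1 (adjusted p = 0.0576) and ADH3 (adjusted p = 0.0701) ended.

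Shifts passed the camera test in 5 further lists, in none of them with an estimated correlation. In the proteasome and ubiquitin list, UBA1, the ubiquitin-activating enzyme, was the 1 of 42 members that rose (1.59-fold, adjusted p = 0.0137), and the median was 0.15 (camera adjusted p = 0.00652, adjusted p = 0.686 with an estimated correlation). In the iron regulon, 2 of 25 members rose. These were FET4, a low-affinity iron transporter (1.67-fold, adjusted p = 0.0355), and TIS11, an mRNA-binding protein of the iron response (1.37-fold, adjusted p = 0.0492), with a list median of 0.19 (camera adjusted p = 0.0279, adjusted p = 0.793 with an estimated correlation). Nuclear genes of respiration had a median of 0.15 over 48 members, 0 of them called and 14 with an unadjusted p under 0.05 (camera adjusted p = 0.0279, adjusted p = 0.793 with an estimated correlation). IDH2, a subunit of isocitrate dehydrogenase, whose row overlaps IRC14, was at 156.8 ± 17.6 and 221.2 ± 3.73 FPKM (adjusted p = 0.0568).

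Ribosomal protein genes had a median of 0.08 over 139 members, 0 of them called and 21 with an unadjusted p under 0.05 (camera adjusted p = 0.044, adjusted p = 0.793 with an estimated correlation). After quantile normalization that median was 0.44, with 57 called higher, while with median centring it was 0.01 and the camera call ended (adjusted p = 0.126). That call also ended at a mean of at least 10 FPKM (adjusted p = 0.174), with ORF rows alone (adjusted p = 0.0854) and with identical rows counted once (adjusted p = 0.0851). Meiosis and sporulation genes had a median of -0.14 over 36 members, 0 of them called by limma and 2 with an unadjusted p under 0.05 (camera adjusted p = 0.0279, adjusted p = 0.765 with an estimated correlation). Quantile normalization ended the camera calls of proteasome (median 0.06, adjusted p = 0.162), iron (adjusted p = 0.138) and meiosis (adjusted p = 0.138). With ORF rows alone those of iron (adjusted p = 0.0663) and respiration (adjusted p = 0.069) ended, the latter also at 10 FPKM (adjusted p = 0.1). SPS4, a sporulation gene, was at 2.73 ± 0.127 and 1.48 ± 0.709 FPKM (adjusted p = 0.146). Leaving out WT replicate 1 ended the camera calls of iron (adjusted p = 0.111), respiration (adjusted p = 0.131), ribosomal proteins (adjusted p = 0.348) and meiosis (adjusted p = 0.0803). Without Asr1-RING replicate 1 those of proteasome (adjusted p = 0.0702), iron (median 0.03, adjusted p = 0.546), ribosomal proteins (adjusted p = 0.0702) and meiosis (adjusted p = 0.122) ended. Without WT replicate 2 that of meiosis (adjusted p = 0.0668) ended, and without Asr1-RING replicate 2 those of respiration (median 0.08, adjusted p = 0.464) and ribosomal proteins (adjusted p = 0.309), while the iron median was 0.29. Respiration had a median of 0.20 with 12 members called higher and 1 lower without Asr1-RING replicate 1, and the proteasome list had 9 called higher. The single-gene calls of UBA1, FET4 and TIS11 ended without WT replicate 1 (adjusted p = 0.155, 0.206 and 0.411) and without WT replicate 2 (adjusted p = 0.0969, 0.221 and 0.275), and that of TIS11 also without Asr1-RING replicate 2 (adjusted p = 0.0641).

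Genes near chromosome ends were described by the 10 outermost rows at each of the 32 chromosome ends, 320 rows of which 271 were tested. Of these 8 rose and 2 fell. PHO12 and PHO11 were the largest rises, followed by PHO89, a sodium-coupled phosphate transporter (3.75-fold, adjusted p = 0.017), and HXK1 with the overlapping YFR052C-A. The others were FET4, the Ty gag row YHR214C-C (adjusted p = 0.0391) and YML131W (adjusted p = 0.0492). The falls were COS12, a member of a subtelomeric membrane protein family, from 3.20 ± 0.28 to 1.12 ± 0.306 FPKM (adjusted p = 0.0224), and the leucine tRNA tL(UAA)B1, from 476.3 ± 51.4 to 191.7 ± 0.0891 FPKM (adjusted p = 0.00248). The set's median log2 difference was 0.08 (quartiles -0.03 and 0.24), against 0.01 for the other rows, and 192 members (70.9%) were above 0, against 52.1% elsewhere. Among ORF rows alone 71.1% of the set were above 0, against 54.9% elsewhere. When ORF rows alone were tested, 4 of the set's 270 rows were called higher and 0 lower.

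The shift of the chromosome-end set passed camera with the preset correlation (p = 0.00574) and not with an estimated one (p = 0.17). The rows it was compared with hold most of the falling tRNA and small nucleolar rows. Among ORF rows alone the set's 270 rows passed camera with the preset correlation (p = 0.0368) and not with an estimated one (p = 0.246). Without the near-identical families the median was 0.13 over 154 rows (p = 0.000442, and p = 0.0309 with an estimated correlation). Higher calls made up 2.95% of the set and 1.84% of the other rows, a difference that did not pass Fisher's exact test, two-sided (8 of 271 against 122 of 6621, odds ratio 1.62, 95% interval 0.677 to 3.34, p = 0.172), with rows that are not independent. By the same exact test they were called lower less often (2 of 271 against 339 of 6621, odds ratio 0.138, 95% interval 0.0165 to 0.507, p = 0.000162). Among ORF rows alone that share was 1 of 270 against 59 of 6247 (odds ratio 0.39, exact p = 0.519). The odds ratio for higher calls was 4.93 (exact p = 0.0317) without WT replicate 2 and 3.06 (exact p = 0.000231) without Asr1-RING replicate 2, so in those settings the subtelomeric share of calls passed the test. The count called higher was 2 without WT replicate 1, PHO11 and PHO12, and was 3 without WT replicate 2, 33 without Asr1-RING replicate 1 and 16 without Asr1-RING replicate 2. The COS12 call ended without WT replicate 1 (adjusted p = 0.0986) or WT replicate 2 (adjusted p = 0.128).

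**Figure D4:**
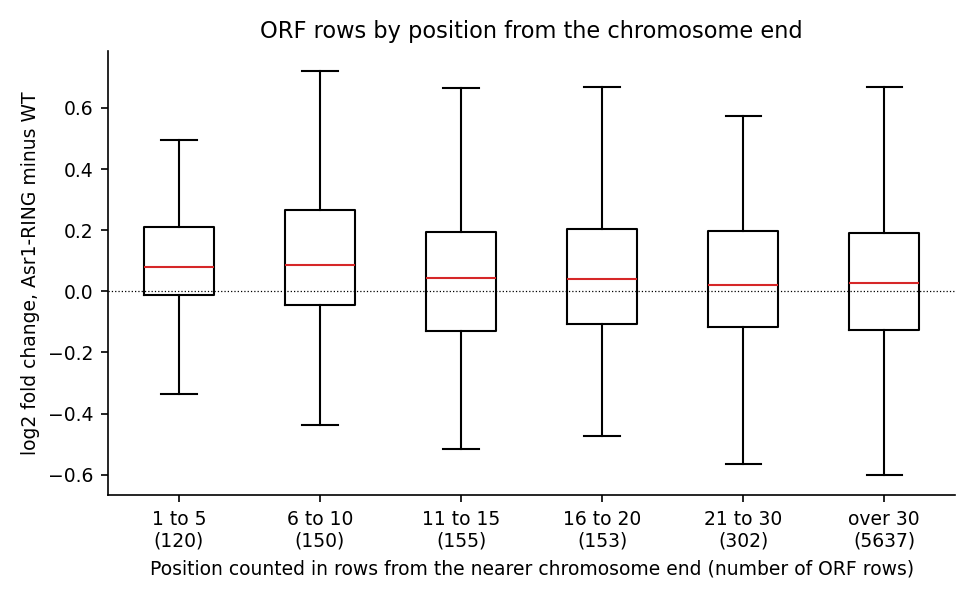
Log2 difference, Asr1-RING minus WT, of tested ORF rows by position counted in rows from the nearer chromosome end, with boxes from the first to the last quartile, a red line at the median, whiskers to the last value within 1.5 box lengths and the number of rows under each box. The median is 0.08 for the 120 rows at positions 1 to 5, 0.09 for the 150 rows at 6 to 10 and 0.03 for the 5637 rows beyond 30.

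The lists of PAU, COS, Y' helicase, flocculin, sugar uptake, and vitamin and thiamine genes did not pass with the settings used throughout. Of their tested members 12 of 23, 11 of 11, 8 of 8, 1 of 7, 14 of 33 and 7 of 27 lay in the outermost 10 rows of a chromosome end. Only the COS and Y' lists therefore describe genes wholly near ends. Of the 23 tested PAU family members, cell wall mannoproteins, only DAN1 rose, from 0.67 ± 0.159 to 2.18 ± 0.11 FPKM (adjusted p = 0.0225, and 0.0661 or 0.104 without WT replicate 1 or 2). The PAU median was 0.06 (camera adjusted p = 0.592), and -0.01 with median centring. The 11 COS genes had a median of 0.08 and a mean of -0.0036 (camera adjusted p = 0.659), COS12 fell, and the median was -0.04 after quantile normalization. With p-values adjusted over the list alone 1 COS gene rose, COS10 (log2 difference 0.50, adjusted p = 0.0641 over all rows, named after its value was seen), and 1 fell. Without Asr1-RING replicate 1 the list also had 1 member called higher. The 8 helicase genes of the Y' elements, near-identical copies, had a median of 0.06 with 0 called by limma and 0 with an unadjusted p under 0.05 (camera adjusted p = 0.231), and a median of -0.01 with median centring. The flocculins, 7 genes, had a median of -0.19 with 0 called and 1 with an unadjusted p under 0.05 (camera adjusted p = 0.63). For sugar uptake the median was 0.17 over 33 genes (camera adjusted p = 0.19). HXT2, a hexose transporter, rose from 236 ± 22 to 505.5 ± 161 FPKM (adjusted p = 0.0496, and 0.197 or 0.231 without WT replicate 1 or 2) and did not pass adjusted over the list alone. Without Asr1-RING replicate 1 the sugar list passed camera (adjusted p = 0.00548) with 9 members called higher, and it passed at a mean of at least 10 FPKM (8 members tested, median 0.37, adjusted p = 0.0471). Vitamin and thiamine genes had a median of 0.09 over 27 genes, 0 called and 3 with an unadjusted p under 0.05 (camera adjusted p = 0.524).

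The remaining lists did not pass camera either. Among 32 telomere silencing factors ABF1, a DNA-binding protein of silencers and origins, fell from 18.8 ± 0.744 to 11.9 ± 1.81 FPKM (adjusted p = 0.0448). Its row overlaps YKL111C, and its call ended without WT replicate 1 (adjusted p = 0.34), WT replicate 2 (adjusted p = 0.214) or Asr1-RING replicate 2 (adjusted p = 0.0526). ABF1 did not pass adjusted over the list alone, and the silencing list's median was -0.06 (camera adjusted p = 0.233). Among 32 mating and cell type genes (median 0.06, and -0.02 with median centring, camera adjusted p = 0.19) and 30 cell wall genes (median 0.03, and -0.04 with median centring, camera adjusted p = 0.291, and 0.000903 after quantile normalization), PRM5, a target of cell wall signalling, rose 1.90-fold (adjusted p = 0.0485). PRM5 did not pass adjusted over either list alone, and its call ended without WT replicate 1 (adjusted p = 0.283) or WT replicate 2 (adjusted p = 0.224). Of 27 heat shock factor targets HSP26 and HSP60, the mitochondrial chaperonin, rose and STI1, a cochaperone of Hsp90, fell (adjusted p = 0.00981, 0.0472 and 0.0278). None of these calls was kept without WT replicate 1 (adjusted p = 0.109, 0.364 and 0.29) or WT replicate 2 (adjusted p = 0.0531, 0.209 and 0.199), and that of HSP60 ended without Asr1-RING replicate 2 too (adjusted p = 0.0785). The median of these targets was -0.0020 and the mean 0.0126 (camera adjusted p = 0.757), with a median of 0.13 after quantile normalization.

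RNA polymerase II subunits, 12 genes, had a median of -0.02 and a mean of 0.0095, with 0 called and 1 with an unadjusted p under 0.05 (camera adjusted p = 0.939), and a median of 0.07 after quantile normalization. Ribosome biogenesis had a median of 0.06 over 103 genes, 0 called and 15 with an unadjusted p under 0.05 (camera adjusted p = 0.0625), and -0.01 with median centring. Without WT replicate 1 or Asr1-RING replicate 2 that list passed camera (adjusted p = 0.00158 and 0.00035), and without the other two its median was below 0 (-0.01 and -0.02). The 11 histone genes had a median of 0.18, 0 called and 3 with an unadjusted p under 0.05 (camera adjusted p = 0.0904), and after quantile normalization 7 were called higher and the list passed (adjusted p = 0.000287). The strain markers had a median of 0.03 over 6 genes, 0 called and 1 with an unadjusted p under 0.05 (camera adjusted p = 0.757), and of -0.05 with median centring and -0.08 after quantile normalization. Mitochondrially encoded genes were not tested, since all 55 mitochondrial rows are listed at 0 in every library. So are 4 rows of the 2-micron plasmid and 19 nuclear rows, among them TDH3, ENO2, TEF1 and TEF2, genes of glycolysis and translation that cells use at high levels, so a value of 0 in this table can be a missing estimate.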

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

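The settings with ORF rows alone and with rows of identical values counted once were chosen after seeing the data. The number of genes higher in Asr1-RING, 130 of those tested, was 63 with no filter, 216 at a mean of at least 10 FPKM, 70 with median centring, 307 after quantile normalization, 256 with robust moderation, 449 at an adjusted p under 0.1, 76 with a fold of at least 1.5 and 36 with ORF rows alone. The number of genes lower in Asr1-RING, 341, was 23 with ORF rows alone and 176 with identical rows counted once. The 341 lower rows hold 185 distinct sets of values, so counting identical rows once accounts for most of the latter drop. With ORF rows alone, leaving out the other rows is not the whole account. On the same 6517 ORF rows, lower calls went from 60 to 23 and higher calls from 127 to 36. For that and the other settings the cause was not tested. Of the 471 calls, 352 were shared with no filter, 439 at 10 FPKM, 411 with median centring, 338 after quantile normalization and 461 with robust moderation. Leaving out each library in turn gave 16 to 781 higher and 197 to 553 lower calls, with a lone library assumed to vary like the other group. A correlation of -0.071 between the groups' deviations by replicate number gives no sign that the numbers pair the libraries. With the replicate number as a block 237 genes were higher and 381 lower. Among named genes 4 gained a call under the block and 2 lost theirs, and higher calls went from 5 to 11 in the stress list, 6 to 9 in amino acid biosynthesis and 8 to 15 near chromosome ends, and lower calls among ribosomal RNA rows from 0 to 6. The cause was not tested.

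The median of the subtelomeric genes stayed above 0 in every setting, at 0.01 with median centring and 0.18 at 10 FPKM. With an estimated correlation it was 0.0848 with p = 0.17. The subtelomeric share of calls, as an odds ratio for higher calls, was 3.54 at a mean of at least 10 FPKM (exact p = 0.000257), 1.91 with robust moderation (exact p = 0.0198), 0.643 after quantile normalization (exact p = 0.291) and 1.09 to 4.93 with each library left out. For lower calls with ORF rows alone it was 0 (exact p = 1). The cause was not tested for any of these.

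Median centring moved every log2 difference by the same amount, taking the median of all tested rows from 0.0179 to -0.0569. Sign changes under it therefore follow from the scaling. Medians of some lists crossed 0 between settings, reaching 0.128 for heat shock factor targets. With median centring they were -0.0109 for the PAU family, -0.01465 for Y' helicases, -0.0185 for mating and cell type, -0.013 for ribosome biogenesis, -0.0412 for cell wall stress and -0.0489 for strain markers, and YRF1-7 was at -0.015. After quantile normalization they were -0.0374 for COS and DUP genes, 0.128 for heat shock factor targets, 0.0699 for RNA polymerase II and -0.0828 for strain markers, with RPL19A at 0.0608 and CAN1 at -0.0417. For heat shock factor targets the median was also 0.00505 with a pseudocount of 5, 0.056 at 10 FPKM and 0.0107 with identical rows counted once, and for strain markers -0.0044 with no filter. Leaving out each library gave -0.036 to 0.0812 for heat shock factor targets, -0.01996 to 0.153 for ribosome biogenesis, -0.0332 to 0.033 for RNA polymerase II, -0.0456 to 0.0381 for strain markers and -0.202 to 0.0436 for UBP3. For the settings other than median centring the cause was not tested. At 10 FPKM the lists of PAU genes, Y' helicases, flocculins and meiosis had too few members left to test. Of the 24 lists, 10 had a camera call with the preset correlation, and all 10 lost it with an estimated correlation. With fry 9 of these 10 lost it, and alcohol metabolism kept it (fry adjusted p = 0.0123). Of 66 named genes with a call, 35 lost it without WT replicate 1, 33 without WT replicate 2, 1 without Asr1-RING replicate 1 and 9 without Asr1-RING replicate 2. With ORF rows alone 19 named calls ended (limma adjusted p = 0.0501 to 0.069). These were YKR075W-A, YPR077C, YPR108W-A, YOR082C, COS12, DAN1, HXT2, FET4, TIS11 and PRM5. The rest were ABF1, HXK1, ALD4, GPH1, STI1, HSP60, ADH3, HIS1 and LEU1. Depth limits values near the floors of 0.079 to 0.091 FPKM per kb, and the table does not say which values of 0 are missing estimates.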

Other observations

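All tests of explanations in this part were chosen after the result was seen, except the test of a shared activator on its other targets, and the Ty and small RNA neighbour groups were formed after seeing the data.

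Rows of the retrotransposon Ty tended upwards in the Asr1-RING libraries, with single-row calls only where they encode the short gag protein. Of 33 tested gag rows 13 rose and 0 fell, with a median log2 difference of 0.75 (quartiles 0.66 and 0.78, camera p = 6.47e-16 with the preset correlation, p = 0.207 with an estimated one). The 44 tested rows of the longer gag-pol fusion, which overlap gag, had 0 calls by limma and a median of 0.15. They too passed camera upwards with the preset correlation (p = 0.00365) and not with an estimated one (p = 0.317). The gag and gag-pol rows were not tested against each other. All of these rows have near-identical copies, and the count called higher was 2 with median centring, after quantile normalization, with no filter or with ORF rows alone, and 26 to 29 at a mean of at least 10 FPKM, with the replicate block or with robust moderation. No gag row was called without WT replicate 1 or without WT replicate 2, against 29 without Asr1-RING replicate 1 and 31 without Asr1-RING replicate 2. ORFs that overlap or lie within 200 bp of a tRNA or small nucleolar RNA row fell more often than others. Where such an ORF overlaps the small RNA row, its reads may be those of the small RNA. The count was 13 of 142, of which 8 overlap, against 47 of 6375 (Fisher's exact test, two-sided, odds ratio 13.5, 95% interval 6.56 to 26.2, p = 3.09e-10). That count was 3 without WT replicate 1, 6 without WT replicate 2, 21 without Asr1-RING replicate 1, 15 without Asr1-RING replicate 2 and 7 with ORF rows alone. LSR1, the U2 RNA of the spliceosome, was listed at 0 in WT replicate 1 and at 19320, 11267 and 10203 FPKM in the other libraries.

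The 471 calls were compared with the other splits of the 4 libraries. Only 1 of the 3 splits into groups of 2, the real one, gave as many, and the highest of the others gave 0 calls by limma, with 87 and 33 rows at an unadjusted p under 0.05. With 3 splits a share under 0.05 cannot be reached.

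For the fall of tRNA and small nucleolar RNA values, a shift of all values by the authors' scaling would move ORFs too, and their median was 0.0301 (quartiles -0.12 and 0.19). Lower output of RNA polymerase III alone would leave the 79 small RNAs made by RNA polymerase II in place, and their median was -0.72, with 53 lower, against -1.43 over the rows made by RNA polymerase III. Lower recovery of short RNA in the mutant libraries may contribute, since the log2 difference of the 81 small nucleolar and spliceosomal rows followed their length (Spearman's rho 0.528 across rows, permutation p = 1e-05, the smallest that 100000 resamples can give). ORF rows of up to 200 bp had a median of -0.07 with 8 of 210 lower, against 0.0301 with 60 of 6517 lower over all ORFs, and an mRNA extends beyond its ORF row. A biological difference between mutant and WT in the making or stability of these RNAs stays open and was not tested.

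Of the 18 members of the phosphate regulon with no near-identical copy 9 rose, against 116 of 6497 other ORFs (Fisher's exact test, two-sided, p = 1.11e-11, median 0.38, quartiles 0.14 and 1.02), which argues against reads shared between copies as the whole account. The 17 members taken as away from chromosome ends lie outside the outermost rows, and include PHO84 at row 13 from its end. Of these 17 members 8 rose (exact p = 2.9e-10, median 0.32). This argues against position within the outermost rows as the whole account, and position further inwards was not tested. Both exact p-values treat the members as independent, although members of this list vary together. Both counts fell to 2, PHO84 and SPL2, without WT replicate 1 or without WT replicate 2, with medians of 0.41 and 0.34 for members with no copy and 0.37 and 0.27 for those away from ends. Less phosphate in the mutant cultures at harvest could give the same picture and cannot be told apart from the genotype, since culture and genotype go together in these libraries (PHO84 differed by 0.67 on the log2 scale between the mutant libraries, against 3.32 between groups). An effect of the RING mutation on phosphate signalling is likewise open as a hypothesis.

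Of 12 reported targets of the activator Yrr1, known from drug resistance, 5 fell, and beside AZR1 and YLL056C these were FLR1, a fluconazole transporter (37.4 ± 0.142 to 19.0 ± 1.09 FPKM, adjusted p = 0.00397), SNG1 (163 ± 7.13 to 87.1 ± 0.257 FPKM, adjusted p = 0.00399) and YLR046C (122.1 ± 3.46 to 58.8 ± 1.06 FPKM, adjusted p = 0.00278). Their calls ended without WT replicate 1 for FLR1 (adjusted p = 0.0607) and SNG1 (adjusted p = 0.0631) and without WT replicate 2 for FLR1 (adjusted p = 0.0502), and that of YLR046C stayed. Their median log2 ratio to the WT mean was -0.96 in 1 mutant library and -1.06 in the other, which decides nothing about a single library as the cause, since the 5 genes were chosen because they had passed. For the same reason the tally of 5 among 12 is no test of enrichment. Lower activity of the shared activator may be a candidate explanation. Its 7 other reported targets had a median of -0.24 with 0 called by limma, which missed the bound of -0.3 set beforehand. The rule also asked for a median below the 5th percentile of random lists matched for expression. That part was met (percentile 0.11 of 10000 lists), and with 1 part missed the question stayed open. Members of the random lists were drawn independently, so the percentile does not allow for targets that vary together. Of these 7 targets, SNQ2 and YLR346C lay below 0 (limma unadjusted p = 0.00558 and 0.00599) and YMR102C above (limma unadjusted p = 0.0191).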
